A study of Mus musculus with 292 samples.

How the data were processed

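Brain RNA of 292 F2 mice was measured on 292 arrays of 2 colours. Per the labels, the mice came from an intercross of F1 animals of the inbred strains C57BL/6J and C3H/HeJ, made in both directions of the cross, and included females and males. They ate a chow with 4% fat until week 8 and then a Western diet with 42% fat and 0.15% cholesterol for 12 weeks, and were killed at 20 weeks after a fast of 12 h. Neither the sex nor the cross direction of any single mouse was given in the sources used here. All 292 arrays therefore formed 1 group. A mouse number was the only numeric label. A spelling difference in the description text split the arrays into 215 of form 1 and 77 of form 2, and nothing in the labels says that this spelling carries a meaning.

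Per the labels' protocols, total RNA was purified on spin columns with DNase, amplified with an automated aminoallyl procedure and labelled with Cy3 for the mouse and Cy5 for the pool on every array, so no dyes were swapped. The pool was made, per the labels, from equal portions of the RNA of every sample. The deposited values were taken as log10 ratios of mouse to pool, 1 per probe and array. The image analysis, background correction, normalization and filters that the authors used are not given in the sources used here, and neither the log base nor the direction of the ratio is stated. Both were therefore examined in the data, as described in the results. No signal intensities were used, so the signal over background behind a ratio is unknown, and only the number of arrays limits the precision that can be stated.

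The table held 23574 probes. It had 0.0433% of its values missing, and 690 values stood at the limits of -2 and 2, which correspond to a 100-fold ratio. The 25 probes missing on more than 5% of the arrays were left out, which left 23549 probes, and 252 remaining missing values were filled with the probe's mean. Array medians lay between -0.0073 and 0.0133, and no further centring was applied in the main setting. The SD over probes of an array had a median of 0.068 and ran from 0.0437 to 0.2. The platform annotation listed 13713 of the probes, of which 48 had several genes and 13665 had 1 gene. Of the latter, 12662 matched a gene of the mouse gene table of assembly GRCm38.p6 by gene identifier and took its present symbol, 1003 did not match, and 9861 probes had no annotation. This gave 10835 named genes. Where a gene had several probes, the probe with the largest SD across mice stood for it. That table served for names and for the order of genes along chromosomes, and no coordinates were used.

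Before any relation across mice was computed, the arrays were searched for batches. Sets of probes missing on at least 20 arrays marked 3 batches. Batch A held 74 arrays of form 1 (mouse numbers 51 to 196), with the same 19 probes missing on each. Batch B held the 77 arrays of form 2 (mouse numbers 54 to 212), with 17 probes missing on each. Batch C held 141 arrays of form 1 (mouse numbers 213 to 362) with no probe missing throughout. The batches were found after the data were seen, and every analysis that uses them was added then. Between-batch differences made up 11.2% of the variance over probes. The first principal component held 15.2% of the variance, and 54.4% of that component lay between batches.

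The tests, the main settings, the named-gene rule, the gene lists and most alternatives were fixed before the data were examined. Each probe's mean log ratio was tested against 0 with limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over 23549 probes. A probe was called away from the pool at an adjusted p under 0.05 and a mean of at least 1.2-fold either way. Trends over mouse number and differences between the description forms were tested with limma at an adjusted p under 0.05. Gaussian mixtures with equal variance and 1 to 3 components were fitted to each probe with mclust 6.1.1. A probe was called clustered where the Bayesian information criterion of 2 or 3 components exceeded that of 1 by more than 10, neighbouring means lay more than 3 within-component SDs apart and every component held at least 5% of the mice. Clusters served to describe a probe, and no other gene was averaged or tested between them.

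For each of 28 gene lists the median Pearson r over pairs of its genes was set against 10000 random lists of the same size, matched on the decile of SD, with a two-sided p and Benjamini-Hochberg adjustment over the lists. The lists were immediate early, glucocorticoid responsive, 2 circadian, myelin, astrocyte, microglia, endothelial, choroid plexus, ependymal, leptomeningeal, erythrocyte, striatal, cerebellar, hypothalamic peptide, thalamic, cortical and hippocampal, olfactory bulb, pituitary, retina and pineal, general neuronal, interferon response, heat shock, cholesterol synthesis, oxidative phosphorylation, ribosomal protein, sex chromosome and strain-variable genes. Each member was correlated with the mean standardised value of the other members, with 100000 permutations of mice. The p was adjusted over all 351 list memberships, a gene in several lists counting in each, and over the list alone. List scores were correlated with each other in the same way over 300 pairs of 25 lists. The pituitary and glucocorticoid responsive scores fell into clusters and entered no pooled relation, and the sex chromosome list was left out of the relations too. The mean squared r of genes was computed by distance in the gene order, leaving out neighbours whose symbols share their first 3 letters.

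The planned chance value for neighbouring genes, 100 circular shifts of the gene order over the genome, turned out to be void. A shift moves all genes together and keeps nearly every neighbour, so its values lay between 0.0727 and 0.0729, beside 0.0729 in the true order. Random orders of the genes, 100 in number, were used in their place after this was seen.

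Named genes followed a fixed rule. It took the 20 genes with the largest SD, the 15 clustered genes with the largest gain of the criterion, the 8 neighbouring pairs with the largest squared r, and per list the 3 members with the highest and the 1 with the lowest r with the rest. It also took the 5 genes with the smallest p in each direction for mouse number and for description form, the 5 genes farthest from the pool in each direction among those called, and clustered members of the strain-variable list. Only probes with 1 gene symbol counted. Xist, Ddx3y and Uty were to be named always but had no named probe among those used here. Genes named outside this rule are said to be so where they appear.

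Each procedure was tested on simulated data. On 23549 simulated probes limma recovered 100% of 200 probes shifted by 0.1 log10 units from the pool with 0 false calls. A shift of 0.05 between the forms was recovered in 92% of 50 probes and one of 0.02 in 24%, with 8 false calls. For mouse number the shares were 100% and 84%, with 7 false calls. The simulated probes were independent of each other. On the real arrays, other orders of the mouse numbers called up to 4835 probes and other splits into forms up to 901. The cluster rule called 0% of 2000 normal and 0.15% of 2000 heavy-tailed single-component probes, and found 98.75% of 400 probes with 2 equal components 3.5 SDs apart and 95.25% of 400 with 3 in shares of 1:2:1. For the cluster rule no skewed values and no steps between batches were simulated. The list test called 5 of 5 lists with a shared r of 0.05 and 0 of 15 without. The permutation test called 50 of 50 correlated and 1 of 50 uncorrelated pairs. The neighbour measure returned 0.043 where 0.0433 was put in. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used.

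Alternatives changed 1 choice at a time. They comprised median centring with equal spread per array, quantile normalization, leaving out the 15 arrays with the largest root mean square log ratio, each description form alone, removal of a linear and quadratic trend over mouse number, regression on the sex chromosome probes, removal of the first principal component, the mean of a gene's probes, Spearman in place of Pearson, array weights, other cluster rules and covariates. Centring within batches, single batches, batch as a covariate, form 2 against batch A alone and the random gene orders were chosen after seeing the data.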

Results

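Gene expression was measured in the brains of 292 F2 mice from an intercross between C57BL/6J and C3H/HeJ, a pair of inbred laboratory strains, made in both directions of the cross. Each mouse was hybridised once against a common pool, and each value was taken as the log10 ratio of that mouse to the pool. The labels put all mice in a single group, so the comparisons open to the data were each mouse with the pool, genes with each other across mice, and the arrays by mouse number and by the form of their description. Of the probes, 23549 were used, and 10835 genes could be named. The median probe had an SD of 0.0495 across mice, which corresponds to 1.12-fold, and the 95th percentile of the probe SDs was 0.115, or 1.3-fold. Pairs of arrays correlated over all probes with a median r of 0.109, from -0.638 to 0.795, and 3.39% of the pairs lay under -0.3. That correlation is across genes, which are not independent replicates. Each mouse is its own animal, with 1 array and no technical repeat, so the spread between mice includes the error of the measurement.

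The genes that differed most from mouse to mouse were Y-linked genes and genes of the anterior pituitary. Eif2s3y, a Y-linked subunit of a translation initiation factor, had an SD of 0.902, and Kdm5d, a Y-linked histone demethylase, had an SD of 0.636. The hormone genes were prolactin (Prl) with 0.852, the shared alpha subunit of the glycoprotein hormones (Cga) with 0.704, growth hormone (Gh) with 0.656, all 3 above Kdm5d, and the beta subunit of thyrotropin (Tshb) with 0.481 (n = 292 for each). Between the 5th and 95th percentile of mice, Prl spanned 282-fold, Cga 102-fold, Gh 63.3-fold and Tshb 31.8-fold. The pheromone receptor gene Vmn2r122 (SD 0.548) and the securin gene Pttg1 (0.499) ranked between Kdm5d and Tshb, and the kidney cotransporter gene Slc12a1 (0.474), Tmprss11a (0.436) and the interferon-inducible GTPase gene Gbp2b (0.431) came after Tshb. The remaining 9 of the 20 most variable genes were Ccnb1ip1 (0.407), Prdm16 (0.382), Olfr707 (0.368), Gprc6a (0.355), Paip1 (0.335), Miox (0.332), Omt2b (0.328), Atp6v1e2 (0.308) and Lrrc6 (0.305). The SD of Miox was 0.0918 in batch A, 0.0797 in batch B and 0.47 in batch C, and that of Gprc6a was 0.0923, 0.242 and 0.473. Omt2b (0.136, 0.265 and 0.419), Olfr707 (0.251, 0.347 and 0.427) and Tmprss11a (0.281, 0.455 and 0.49) also had their largest SD in batch C. Not all genes did: Gbp2b (0.469, 0.443 and 0.39) and Lrrc6 (0.303, 0.298 and 0.287) had their smallest SD there.

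The comparison with the pool asked which genes lay off the average of all mice that the pool was described to hold. Prl lay 7.19-fold below the pool in the mean log10 ratio (-0.857 ± 0.0496, SE, n = 292; limma adjusted p = 2.44e-42), and 226 of 292 mice were below it. Cga was 3.06-fold lower (-0.486 ± 0.041, adjusted p = 6.27e-25, 206 mice below) and Gh 2.56-fold lower (-0.408 ± 0.0382, adjusted p = 2.19e-21, 204 mice below). The Y-linked genes Eif2s3y (-0.699 ± 0.0525, adjusted p = 3.18e-29, 162 mice below) and Kdm5d (-0.412 ± 0.037, adjusted p = 1.06e-22, 142 mice below) were the other genes at the lower end. A mean log lies below the log of the mean, and further below it the wider the spread between mice. These genes were the 5 with the largest SD. Their low mean logs and p-values therefore do not show that they lay below the average of all mice. The mean linear ratio was 0.917 for Prl, 1.21 for Cga, 1.31 for Gh, 0.79 for Eif2s3y and 0.861 for Kdm5d.

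At the upper end of that comparison the differences were small and came from batch C. The zinc finger gene Zfp638 was 1.26-fold above the pool (0.101 ± 0.00821, SE, n = 292; limma adjusted p = 3.38e-26, 209 mice above), with means of -0.0153 in batch A, -0.00601 in batch B and 0.22 in batch C. Zfp958 (1.23-fold, adjusted p = 5.34e-32, 218 mice above), the extracellular matrix gene Postn (1.22-fold, adjusted p = 3.63e-22, 218 mice), the autophagy gene Rb1cc1 (1.22-fold, adjusted p = 1.04e-23, 211 mice) and Gm14288 (1.22-fold, adjusted p = 5.62e-28, 211 mice) showed the same split, with batch C means of 0.181, 0.189, 0.186 and 0.177. In all, 138 probes were called, 25 higher and 113 lower than the pool in the mean log ratio. In single batches limma called 33 probes in batch A, all lower, 33 in batch B (8 higher, 25 lower) and 1638 in batch C (816 higher, 822 lower). With array weights the count was 346, of which 42.5% were higher, against 18.1% in the main setting, and with no fold threshold 16104 probes were called.

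Some genes took a few discrete levels rather than a single spread. In an intercross 1 locus of large effect can give such levels, but most called probes did not have the shares of a freely segregating locus. Pttg1, which encodes securin, a guardian of sister chromatids, had 3 clusters at -1, -0.003 and 0.266, holding 27.7%, 49% and 23.3% of mice, with a within-cluster SD of 0.0342 and an 18.4-fold step from lowest to highest. The ribosomal protein gene Rps3 had clusters at -0.403, 0.0104 and 0.221 (24.7%, 51.4% and 24% of mice). Another probe of Rps3 had r = 0.295 with this one and was not called clustered, so these levels are those of 1 probe. The secretory granule chaperone gene Scg5 had clusters at -0.272, 0.0243 and 0.183 (22.6%, 56.2% and 21.2%). Further genes with 3 clusters among the 15 with the strongest evidence were the chemokine receptor gene Ccr6 (4.92-fold from lowest to highest cluster), the chloride channel gene Best1 (4.2-fold), Mro (5.18-fold), the spliceosome gene Aqr (4.9-fold), the diacylglycerol kinase gene Dgkq (2.08-fold), the nucleotidase gene Bpnt1 (2.32-fold) and Cga (33.4-fold). The clusters of Cga held 60.3%, 11.6% and 28.1% of mice, those of Aqr 21.2%, 61% and 17.8%, and those of Ccr6 27.7%, 54.8% and 17.5%.

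**Figure D1:**
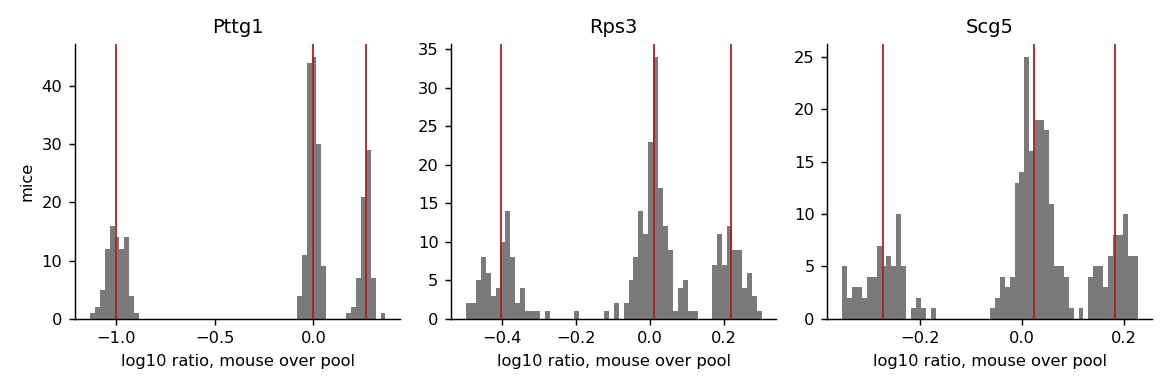
Number of mice (n = 292) by log10 ratio of mouse over pool for Pttg1, Rps3 and Scg5, with red lines at the fitted cluster means. The 3 clusters of Pttg1 stand at -1, -0.003 and 0.266, and those of Rps3 at -0.403, 0.0104 and 0.221.

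Genes with 2 clusters had other proportions. The crossover gene Ccnb1ip1 had 25.7% of mice at -0.755 and 74.3% at 0.108, and the translation factor partner Paip1 had 22.3% at -0.697 and 77.7% at 0.0432. Taf8, a subunit of the general transcription factor TFIID, had 84.9% at -0.0841 and 15.1% at 0.297. Gh had 68.5% of mice at -0.824 and 31.5% at 0.486, and Kdm5d had 47.6% at -1.06 and 52.4% at 0.178. Over all probes 1547 (6.57%) were called, 1453 with 2 clusters and 94 with 3, among them 775 named genes. The count depends on the rule: it was 3665 with means more than 2 SDs apart and 114 with more than 4, 308 with unequal variances (168 of them among the 1547) and 967 with arrays scaled to equal spread (589 among the 1547). The outer clusters of a called probe lay a median 1.32-fold apart. Probes with 3 clusters had median shares of 24.7%, 52.4% and 21.8%, beside 25%, 50% and 25% for a locus that segregates freely, and 65 of the 94 did not depart from those shares after adjustment. Among the probes with 2 clusters the smaller cluster held under 15% of mice in 1061, between 20% and 30% in 157 and at least 40% in 28. A share under 15% is not one that such a locus gives. In each batch alone 93 of the 1547 probes were called again, 43 of them with 3 clusters over all mice. Of the 15 named genes, Pttg1, Rps3, Scg5 and Bpnt1 kept their call in each of the 10 alternatives, Ccr6 and Aqr lost theirs in 5 each and Kdm5d in 3, and Cga, Ccnb1ip1 and Dgkq lost theirs in 2. Gh, Best1, Mro, Taf8 and Paip1 lost theirs in 1 each. A call counted as kept whatever its number of clusters, and that number was less stable. With arrays scaled to equal spread, Pttg1, Best1, Mro and Cga had 2 clusters, and Cga had 2 in form 2 as well. Paip1 had 3 with unequal variances and in each batch alone, Ccnb1ip1 3 with unequal variances and in form 2, and Kdm5d 3 with batch centring.

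The level of the Y-linked genes split the mice by array batch. Eif2s3y was fitted with components at -1.63, 0.036 and 0.268 holding 47.6%, 26.7% and 25.7% of mice, and the upper pair lay only 2.32 within-component SDs apart, so that the gene did not meet the cluster rule. In batch A 98.6% of mice were at -1.62, and in batch B 98.7% were at 0.278. Batch C had 46.1% at -1.65 and 53.9% at 0.0212. Kdm5d gave 98.6% at -1.12 in batch A, 98.7% at 0.25 in batch B, and in batch C 46.1% at -0.995 and 53.9% at 0.104. In the upper cluster of batch C both genes were thus below the level of batch B, by unequal steps. Hccs, an X-linked gene for a haem lyase of cytochrome c, had medians of -0.0921 in batch A, 0.0816 in batch B and -0.132 in batch C, with no split within batch C.

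**Figure D2:**
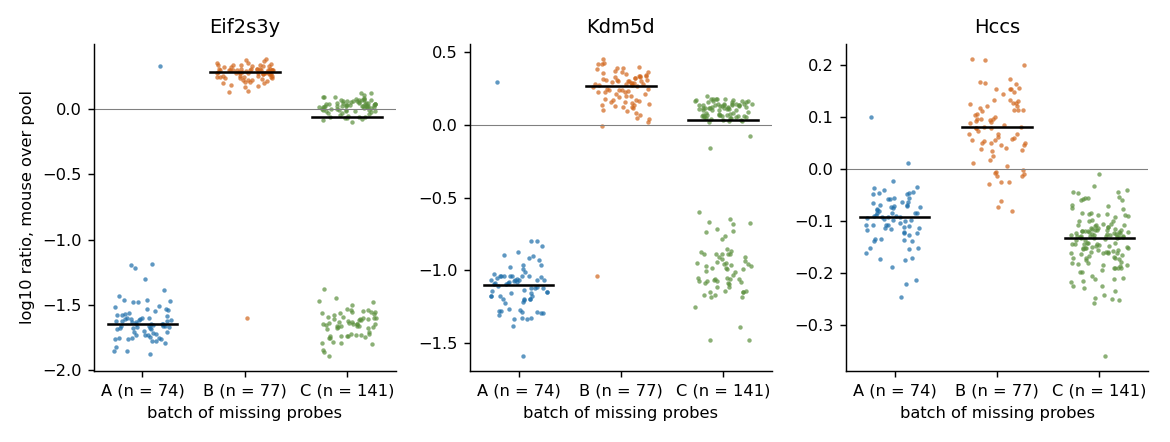
Log10 ratio of mouse over pool for Eif2s3y, Kdm5d and Hccs, 1 point per mouse, by batch of missing probes (A, n = 74; B, n = 77; C, n = 141), with a black line at the median. Eif2s3y is near -1.62 in batch A, near 0.278 in batch B and at both -1.65 and 0.0212 in batch C.

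The direction and the base of the deposited ratio were examined because the labels give the dyes but not which way the values run. In the true direction, a pool of equal portions fixes the mean linear ratio at 1. Of the 236 probes in the top 1% by SD, 155 (65.7%) had a mean linear ratio nearer 1 as deposited than with the sign turned, with median means of 1.2 and 1.4. The share was 55.9% of the top 5% and 46.1% of all 23549 probes, so this measure alone did not settle the direction. Over batches A and B only, a choice made after the data were seen, 75% of the top 1% were nearer 1 as deposited. For the 94 probes with 3 clusters, also examined after the fact, the linear ratios of the lowest and highest cluster summed to within 0.2 of 2 in 90.4% as deposited and in 27.7% with the sign turned. Eif2s3y had a mean linear ratio over batches A and B of 0.987 as deposited, against 21.8 with the sign turned, 0.779 with base 2 and 0.772 with base e, and for Kdm5d these values were 0.973, 7.12, 0.835 and 0.82. Over all 292 mice, which the pool was described to hold, Eif2s3y had 0.79, 21.6, 0.738 and 0.709 and Kdm5d 0.861, 6.29, 0.824 and 0.797, so base 10 was nearest 1 there by a smaller margin. The 3-cluster sums did not favour base 10: they lay within 0.2 of 2 in 90.4%, 98.9% and 96.8% for base 10, 2 and e. A smaller base draws every ratio towards 1, so this share cannot decide the base. Half-sums over the middle cluster had medians of 1, 0.987 and 0.985. The base thus rests on the mean ratios of the Y-linked genes. Directions in all parts are given as mouse over pool in base 10, which is likely from these values but is not stated in the labels and rests in part on measures chosen after the data were seen. With the sign turned, every higher would read lower, and correlations, clusters and counts of calls would stay as they are, while mean linear ratios would change.

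Of the 28 gene lists, 14 varied together across mice more than random lists of equal size and SD. The question was which functions, cell types and regions rise and fall jointly from brain to brain. A gene in several lists counts in each of them. Of the 351 list memberships, 243 moved with the rest of their list, 28 against it and 80 did not pass. Adjusted over the list alone, 242 moved with and 27 against. The smallest p that random lists can give is 0.0002, which is 0.0008 after adjustment, and the smallest from 100000 permutations is 1e-05, or 1.9e-05 adjusted over the 351 members. Of the 84 members named below that passed and had a single level, 80 had the same sign of r in each of the 3 batches and 81 also passed by rank. Leaving out the 2 mice farthest from the median of the list kept the sign of r in 83 of the 84. The size of r was less stable than its sign: it was more than 1.5 times smaller than over all mice, or of the other sign, for 8 of the 84 in batch A, 7 in batch B and 25 in batch C.

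**Figure D3:**
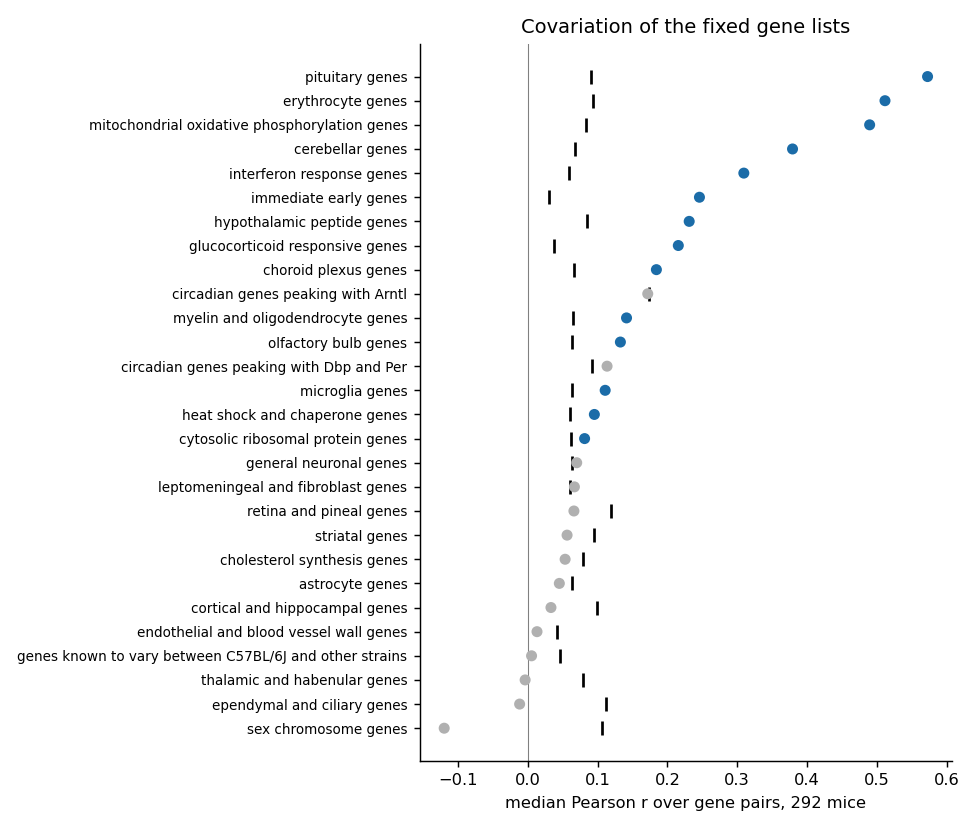
Median Pearson r over gene pairs of each list across 292 mice (points, blue where the adjusted p was under 0.05, grey otherwise) and the upper limit of the central 95% of random lists (black ticks). The pituitary, erythrocyte and oxidative phosphorylation lists have the highest medians, and the point of the sex chromosome list lies lowest, at -0.12.

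Genes that neurons switch on within minutes of activity moved as a block. The immediate early list had a median r of 0.246 (adjusted p = 0.0008), 19 of 21 measured genes moved with it (20 adjusted over the list alone) and 2 did not pass. Arc, a synaptic protein gene, followed the others with r = 0.814 and rho = 0.834, Egr2 with r = 0.739 and rho = 0.75, and Egr4 with r = 0.733 and rho = 0.741, while Atf3 stood at r = -0.0789 (adjusted p = 0.213). Glucocorticoid responsive genes fell into clusters as a score, 26% of mice being in the lower cluster, 47.3% in batch A, 36.4% in batch B and 9.22% in batch C, so no pooled r is given. The 2 clusters lay 3.06 within-cluster SDs apart, just over the limit of 3, so the call is borderline. The list test of these genes passed with an adjusted p of 0.0008, and 13 of 15 genes moved with the rest (13 over the list alone), led by Tsc22d3, Cdkn1a and Map3k6. Within the clusters the median pairwise r was 0.0665 and 0.0725. The score that sets the clusters is the mean of the same genes, which lowers r inside them. These values thus do not show how far the genes covary apart from the split. Zbtb16 had the lowest r of that list (adjusted p = 0.877).

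Clock genes were borderline as lists. Those peaking with Dbp and the Per genes had a median r of 0.113 (adjusted p = 0.0508), and 7 of 10 moved with the rest (7 over the list alone), with Dbp at r = 0.548 and rho = 0.524, Per2 at r = 0.481 and rho = 0.495, Bhlhe40 at r = 0.361 and rho = 0.4, and Nr1d1 at r = 0.0464 (adjusted p = 0.476). Those peaking with Arntl had a median r of 0.172 (adjusted p = 0.0757), and 5 of 6 moved with the rest (5 over the list alone). Within batch C the medians of the 2 lists were 0.0232 and 0.103. Arntl itself had r = 0.647 and rho = 0.613, the repressor gene Nfil3 r = 0.576 and rho = 0.564, Cry1 r = 0.417 and rho = 0.377, and Clock r = 0.0249 (adjusted p = 0.692). Within batches A, B and C the r of Arntl was 0.695, 0.769 and 0.278, that of Cry1 0.348, 0.57 and 0.142 and that of Dbp 0.59, 0.6 and 0.322.

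Among glia, myelin and microglia genes covaried and astrocyte genes did not pass as a list. Myelin and oligodendrocyte genes had a median r of 0.141 (adjusted p = 0.0061), and 14 of 15 moved together (14 over the list alone). The median was 0.158, 0.109 and 0.0644 within batches A, B and C (adjusted p = 0.0452 in batch C). Cnp, a myelin phosphodiesterase gene, had r = 0.703 and rho = 0.708 (r = 0.427 in batch C), Sox10 r = 0.556 and rho = 0.558, Gjb1 r = 0.515 and rho = 0.552, and Mal r = -0.0701 (adjusted p = 0.265). Microglia genes had a median r of 0.111 (adjusted p = 0.0177), with 10 of 14 together (10 over the list alone): Trem2 had r = 0.682 and rho = 0.659, the complement gene C1qa r = 0.566 and rho = 0.562, Tmem119 r = 0.558 and rho = 0.539, and Ctss r = -0.0396 (adjusted p = 0.539). Astrocyte genes had a median r of 0.045 (adjusted p = 0.156), 5 of 13 moving with the rest and 1 against (5 and 0 over the list alone). Acsbg1 had r = 0.511 and rho = 0.537, the glutamate transporter gene Slc1a3 r = 0.409 and rho = 0.413, and the connexin gene Gja1 r = -0.125 and rho = -0.163. Slc4a4 had 2 clusters, within which r was 0.149 and 0.046.

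Blood and fluid compartments differed in how tightly their genes moved. Erythrocyte genes had a median r of 0.512 (adjusted p = 0.0008) and all 7 moved together (7 over the list alone). The globin genes Hbb-b1 and Hbb-b2 had r = 0.917 and 0.914 with the rest (rho = 0.922 and 0.902), and Bpgm had r = 0.224 and rho = 0.208. The haem synthesis gene Alas2 had 2 clusters, with r = 0.831 and 0.739 inside them. Choroid plexus genes had a median r of 0.184 (adjusted p = 0.0044), 9 of 13 moving with the rest and 1 against (9 and 1 over the list alone). Transthyretin (Ttr) had r = 0.684 and rho = 0.608, the folate receptor gene Folr1 r = 0.6 and rho = 0.566, F5 r = 0.592 and rho = 0.592, and the claudin gene Cldn2 moved against them with r = -0.213 and rho = -0.259. Endothelial and vessel wall genes (median r = 0.013, adjusted p = 0.394) had 10 of 18 members with the rest and 2 against (10 and 2 over the list alone). The mural cell genes Pdgfrb (r = 0.433, rho = 0.424), Acta2 (r = 0.346, rho = 0.311) and Tagln (r = 0.335, rho = 0.304) led, and the glucose transporter gene Slc2a1 opposed them (r = -0.334, rho = -0.323). Leptomeningeal genes had a median r of 0.0666 (adjusted p = 0.0597) with 9 of 15 together (9 over the list alone), led by Crabp2 (r = 0.484, rho = 0.48), Slc6a13 (r = 0.344, rho = 0.305) and Igf2 (r = 0.318, rho = 0.349), with Col1a2 at r = 0.000377 (adjusted p = 0.998). Ependymal genes had a median r of -0.0119 (adjusted p = 0.934), 2 of 8 with the rest and 4 against (2 and 4 over the list alone). Mia had r = 0.16 (rho = 0.117) but -0.052 in batch A, Tekt1 r = 0.147 (rho = 0.0919, p = 0.116), Dnah5 r = -0.0404 (adjusted p = 0.532), and the ciliary regulator Foxj1 r = -0.291 (rho = -0.275), with -0.19, 0.012 and 0.24 within batches A, B and C.

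Over all mice, regional genes covaried most for the cerebellum and the hypothalamus, an order that did not hold in batch C. Cerebellar genes had a median r of 0.379 (adjusted p = 0.0008) and all 14 moved together (14 over the list alone). A large part of this came from 2 mice. In mouse 78 (batch B) and mouse 108 (batch A) the cerebellar score was -6.61 and -6.13 SDs, the next lowest was -2.01 and the median mouse 0.046. The granule cell receptor gene Gabra6, named after its values were seen, was at -1.51 and -1.2 in these mice. Without them the median r was 0.184. Il16 then went from r = 0.825 (rho = 0.524) to 0.576, the Purkinje cell gene Pcp2 from 0.809 (rho = 0.661) to 0.673, En2 from 0.765 (rho = 0.491) to 0.52, and Calb1 from 0.355 (rho = -0.0723, p = 0.217) to -0.0176, so that the relation of Calb1 rests on these mice. In batch C, which holds neither, the median r was 0.0902.

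Hypothalamic peptide genes had a median r of 0.231 (adjusted p = 0.0021), and 10 of 11 moved together (10 over the list alone). Oxytocin (Oxt) had r = 0.746 and rho = 0.72, neuropeptide Y (Npy) r = 0.626 and rho = 0.566, somatostatin (Sst) r = 0.623 and rho = 0.622, and histidine decarboxylase (Hdc) r = 0.0313 (adjusted p = 0.63). After removal of the first principal component the median r was 0.0626 and the list no longer passed (adjusted p = 0.096), against 0.127 for olfactory bulb and 0.105 for striatal genes. In batch C it was 0.0907 (adjusted p = 0.053), against 0.116 for olfactory bulb and 0.12 for striatal genes. Olfactory bulb genes had a median r of 0.133 (adjusted p = 0.0056), with 10 of 13 together (10 over the list alone). The mitral cell gene Tbx21 had r = 0.62 and rho = 0.591, Cdhr1 r = 0.592 and rho = 0.572, Dlx2 r = 0.544 and rho = 0.521, and tyrosine hydroxylase (Th) r = 0.0547 (adjusted p = 0.393).

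The other neural lists did not pass. Striatal genes had a median r of 0.0561 (adjusted p = 0.215), with 7 of 12 together and 1 against (7 and 1 over the list alone). The dopamine receptor gene Drd2 had r = 0.432 and rho = 0.461, Rgs9 r = 0.361 and rho = 0.305, and the tachykinin gene Tac1 r = -0.182 and rho = -0.225, although Tac1 had 0.14 within batch A. Ppp1r1b had 2 clusters, with r = 0.283 and -0.103 inside them. Thalamic and habenular genes had a median r of -0.004 (adjusted p = 0.934), 5 of 11 with and 4 against (5 and 4 over the list alone), with Rora at r = 0.231 (rho = 0.235), Pou4f1 at r = 0.211 (rho = 0.261), Calb2 at r = -0.291 (rho = -0.302) and Rgs16 at 0.38 and -0.15 inside its 2 clusters. Cortical and hippocampal genes had a median r of 0.033 (adjusted p = 0.394), 6 of 12 with and 3 against (6 and 3 over the list alone), with Camk2a at r = 0.36 (rho = 0.292), Prox1 at r = 0.317 (rho = 0.298), Tbr1 at r = 0.311 (rho = 0.303) and Tdo2 at r = -0.234 (rho = -0.189). Retina and pineal genes (median r = 0.0659, adjusted p = 0.221) had 6 of 9 with and 1 against (6 and 1 over the list alone). There the melatonin synthesis gene Aanat stood at r = 0.347 (rho = 0.334), Sag at r = 0.298 (rho = 0.398), Rcvrn at r = 0.295 (rho = 0.317) and Gnat1 at r = -0.263 (rho = -0.265). General neuronal genes (median r = 0.0699, adjusted p = 0.0597) had 6 of 13 with and 1 against (6 and 1 over the list alone), with Thy1 at r = 0.478 (rho = 0.454), Syt1 at r = 0.454 (rho = 0.469), Nefm at r = 0.431 (rho = 0.432) and Gad2 at r = -0.168 (rho = -0.167).

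Pituitary genes split the mice into a low and a high cluster, and the same mice were high for several hormones. As a score the list had 2 clusters 4.44 within-cluster SDs apart, with 31.2% of mice in the high one, 36.5% in batch A, 26% in batch B and 31.2% in batch C. Gh, Prl, Tshb, Cga and Pitx1, a transcription factor gene of the pituitary lineage, each fell into clusters of their own. Over the 10 pairs of these 5 genes, 88.4% to 96.9% of mice lay in matching clusters, beside at most 60.8% by chance, and 66 mice were high for all 5 and 181 for none. Lhb and Ghrhr, named outside the rule, and Chga had a single level, with SDs of 0.0362, 0.059 and 0.0758. The list test passed (adjusted p = 0.0008) and 7 of 8 genes moved with the rest (7 over the list alone), Chga not passing (adjusted p = 0.141). No pooled r is given. Within the low and the high cluster of the score the median pairwise r was 0.109 and 0.159, lowered by the split on the mean of the same genes. Inside its own clusters Pitx1 had r = 0.705 and 0.763 with the rest of the list, Gh 0.492 and 0.685, and Cga 0.446, 0.577 and 0.606.

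**Figure D4:**
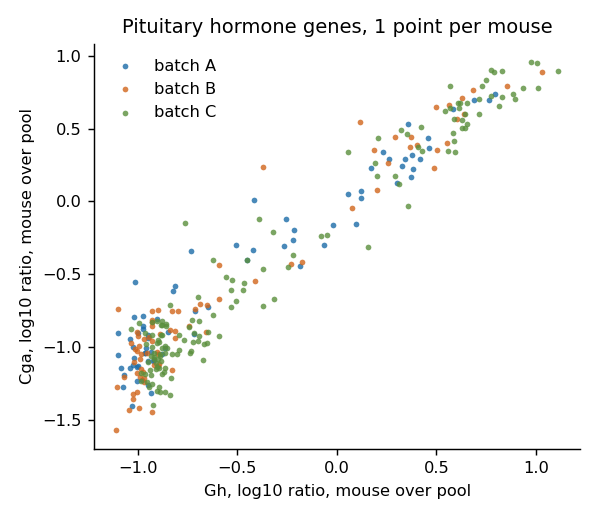
Log10 ratio of mouse over pool of Cga against Gh, 1 point per mouse (n = 292), coloured by batch. Points gather at the low end of both genes and at the high end of both, in each of the 3 batches, and 95.9% of mice lie in matching clusters of this pair.

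Among cellular processes, respiration and the interferon response covaried strongly. Oxidative phosphorylation genes had a median r of 0.49 (adjusted p = 0.0008), with 10 of 12 together and 2 against (10 and 2 over the list alone). The complex I genes Ndufa1 (r = 0.867, rho = 0.855) and Ndufa2 (r = 0.727, rho = 0.721) and the cytochrome oxidase gene Cox7b (r = 0.854, rho = 0.858) led, and the ATP synthase gene Atp5c1 opposed them (r = -0.318, rho = -0.292). Interferon response genes had a median r of 0.309 (adjusted p = 0.0008), and 14 of 16 moved together (14 over the list alone). Oasl2 had r = 0.779 and rho = 0.75, Rtp4 r = 0.77 and rho = 0.751, Usp18 r = 0.733 and rho = 0.717, and Oas1a r = 0.0291 (adjusted p = 0.65). Heat shock genes had a median r of 0.0952 (adjusted p = 0.0211) with 11 of 14 together (11 over the list alone), led by Hsph1 (r = 0.592, rho = 0.574), Hsp90b1 (r = 0.58, rho = 0.547) and Hspb1 (r = 0.454, rho = 0.351), with Hspe1 at r = -0.00959 (adjusted p = 0.885). Cytosolic ribosomal protein genes had a median r of 0.0812 (adjusted p = 0.0384) with 11 of 16 together and 1 against (11 and 1 over the list alone). Rps15 had r = 0.635 and rho = 0.607, Rpl7 r = 0.619 and rho = 0.626, Rps24 r = 0.517 and rho = 0.549, and Rpl13 r = -0.383 and rho = -0.379. The ribosomal list lost its call in 10 of its alternatives, with a median r of 0.0516, 0.0292 and 0.0567 within batches A, B and C, and Rpl13 had r = 0.116 in batch C. Cholesterol synthesis genes (median r = 0.0533, adjusted p = 0.181) had 8 of 13 together (8 over the list alone), with Idi1 at r = 0.455 (rho = 0.484), Sqle at r = 0.376 (rho = 0.385), Nsdhl at r = 0.343 (rho = 0.341) and lanosterol synthase (Lss) at r = -0.042 (adjusted p = 0.523).

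Sex chromosome genes, which entered no relation between lists, did not pass as a list (adjusted p = 0.0597), and 5 of 6 moved against the rest (5 over the list alone). The X-linked genes Ddx3x, Kdm6a and Eif2s3x had medians of 0.053, 0.0725 and 0.0358 in batch A, -0.0593, -0.0586 and -0.0264 in batch B and 0.062, 0.0366 and 0.0193 in batch C. Strain-variable genes, picked for known differences between C57BL/6J and other strains, had a median r of 0.0052 (adjusted p = 0.669), with 8 of 16 together and 2 against (6 and 2 over the list alone). Hbb-b1 had r = 0.398 and rho = 0.391, Hbb-b2 r = 0.392 and rho = 0.394, the class II gene H2-Eb1 r = 0.329 and rho = 0.279, and Wdfy1 r = -0.287 and rho = -0.285. Ide, the gene of insulin-degrading enzyme, was the only member in clusters, with 20.2% of mice at -0.0768 and 79.8% at 0.028, and was called again in batch A alone but in neither other batch.

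Scores of whole lists were then compared across mice, to see which of them moved jointly or apart. A score is the mean of its members whether or not these varied together, and the striatal, cortical, vessel, cholesterol synthesis, strain-variable and Arntl-phase lists had not passed as lists. The strain-variable list holds several histocompatibility genes, such as H2-Eb1. Its relations therefore cannot be read as relations of strain differences. The striatal and hypothalamic scores moved together (r = 0.55, rho = 0.537), as did those of Arntl-phase clock genes and cortical genes (r = 0.545, rho = 0.547), olfactory bulb and oxidative phosphorylation genes (r = 0.533, rho = 0.564), microglia and hypothalamic genes (r = 0.525, rho = 0.5) and interferon and strain-variable genes (r = 0.521, rho = 0.498). The ribosomal protein score moved against the scores of cortical genes (r = -0.503, rho = -0.481), myelin genes (r = -0.497, rho = -0.516) and Arntl-phase genes (r = -0.474, rho = -0.44). The oxidative phosphorylation score moved against those of vessel genes (r = -0.496, rho = -0.495) and cholesterol synthesis genes (r = -0.477, rho = -0.487). For each of these 10 relations the permutation p was 1e-05 for r and rho, the smallest the permutations can give, or 4.5e-05 and 4.3e-05 adjusted over 300 pairs (n = 292).

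Without the 2 mice farthest from the median of the first score, r was 0.527, 0.534, 0.577, 0.523 and 0.526 for the positive relations in the order given. For the negative relations it was -0.502, -0.512 and -0.478 with the ribosomal genes and -0.504 and -0.492 with oxidative phosphorylation. After removal of the first principal component the microglia and hypothalamic relation fell to 0.242 (adjusted p = 0.000171) and that of ribosomal with myelin genes to -0.308. The other positive relations were then 0.472, 0.503, 0.469 and 0.49 in the same order, and the other negative ones -0.409 and -0.403 with cortical and Arntl-phase genes and -0.461 and -0.507 with vessel and cholesterol synthesis genes. Within batches A, B and C the striatal and hypothalamic relation was 0.619, 0.464 and 0.597, Arntl-phase with cortical genes 0.431, 0.473 and 0.48, and olfactory bulb with oxidative phosphorylation 0.498, 0.527 and 0.508. Microglia with hypothalamic genes gave 0.458, 0.612 and 0.378, and interferon with strain-variable genes 0.553, 0.595 and 0.489. Ribosomal genes gave -0.528, -0.541 and -0.306 with cortical, -0.363, -0.311 and -0.274 with myelin, and -0.361, -0.391 and -0.237 with Arntl-phase genes. The vessel relation was -0.591, -0.592 and -0.294, and the cholesterol relation -0.586, -0.513 and -0.333. Of the 300 pairs, 165 passed over all mice, 95 positive and 70 negative, and 153 of them passed by rank. The sign was the same in each batch for 131 of the 165, and 30 passed in each batch.

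Genes next to each other on a chromosome covaried more than genes far apart. Neighbouring loci are inherited together in an intercross, but whether this gives the pattern was not tested. The most similar neighbours were the Y-linked pair Kdm5d and Eif2s3y, with r = 0.36 and 0.62 inside the clusters of Kdm5d, and Gcc2 with the nuclear pore gene Ranbp2, with r = 0.85 and 0.82 inside the clusters of Ranbp2. Pnpt1 and Mtif2, genes of mitochondrial RNA processing and translation, had r = 0.934 over all mice (0.939, 0.909 and 0.943 in batches A, B and C). The Y-linked genes Ssty1 and Gm20747 shared their cluster in 96.2% of mice, the polycomb gene Phf1 and the cell death gene Bak1 in 95.9%, and Tpgs1 and Cdc34 in 94.2%. Within batches A, B and C, in none of which Tpgs1, Cdc34, Lama2 or Ranbp2 was called clustered, r was 0.926, 0.854 and 0.405 for Tpgs1 with Cdc34, 0.878, 0.853 and 0.502 for Arhgap18 with Lama2 and 0.924, 0.94 and 0.806 for Gcc2 with Ranbp2. Gak and Dgkq had r = 0.22, 0.28 and 0.31 inside the clusters of Dgkq, and Arhgap18 and the laminin gene Lama2 r = 0.63 and 0.71 inside those of Lama2.

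Over 9731 adjacent pairs the mean squared r was 0.0729. It was 0.0682 at 2 to 5 genes apart, 0.0653 at 6 to 20, 0.0625 at 21 to 100, 0.061 at over 100 genes on the same chromosome and 0.06 on different chromosomes. The highest of 100 random gene orders gave 0.0624 at distance 1 (p = 0.0099, the smallest they can give). Of 20 chromosomes, 18 had a mean at distance 1 above that between chromosomes, with a range of 0.0577 to 0.0908 and an SD of 0.0086. Chromosome Y, with 6 adjacent pairs and a mean of 0.32, is not among these 20. Of the adjacent pairs, 109 (1.12%) had a squared r over 0.5, and the median pair was at 0.0263. Genes are not independent replicates, and the p describes these 292 arrays.

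**Figure D5:**
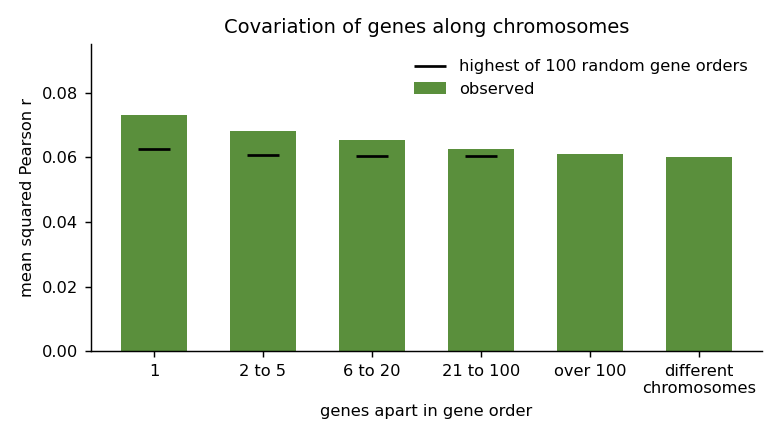
Mean squared Pearson r across 292 mice of gene pairs by their distance in the gene order (bars) and the highest of 100 random gene orders (black lines, drawn up to 100 genes apart). The bars fall from 0.0729 for adjacent genes to 0.06 for genes on different chromosomes.

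Mouse number and description form were compared as checks for batches. Over mouse number the ubiquitin ligase gene Ttc3 rose by 0.0946 ± 0.00457 log10 units per 100 numbers (SE, n = 292; limma adjusted p = 2.37e-55), Anapc16, a subunit of the anaphase-promoting complex, by 0.0614 ± 0.00297, the Golgi protein gene Golm1 by 0.0547 ± 0.00279, the calmodulin regulator Pcp4 by 0.0833 ± 0.00437 and the centrosomal gene Ofd1 by 0.0713 ± 0.00381. Spsb4 fell by 0.0647 ± 0.00336 (adjusted p = 1.15e-50), the potassium channel gene Kcnj14 by 0.0827, the VEGF receptor gene Kdr by 0.112, the transcription factor gene Gata3 by 0.0498 and the vessel adhesion gene Mcam by 0.032. These trends were largely steps between batches: Ttc3 averaged -0.0326 in batch A, -0.0328 in batch B and 0.157 in batch C, and Kdr 0.000225, -0.0285 and -0.183. With the batch as a covariate, Ttc3 (limma adjusted p = 0.267), Ofd1 (0.257) and Gata3 (0.0873) no longer passed. The other named genes did: Golm1 (4.44e-09), Kdr (1.22e-15), Kcnj14 (1.17e-11), Mcam (2.66e-07), Spsb4 (2.44e-05), Anapc16 (0.00817) and Pcp4 (0.0133). These p-values do not give the direction of the trend that remains. In all 14680 probes had a trend, 6713 upward and 7967 downward. The count was 4248 with the batch as a covariate, and 3003, 5087 and 5968 within batches A, B and C. No other orders of the mouse numbers were run in these settings, so these counts have no chance value. Over all 292 arrays, other orders called up to 4835 probes.

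Between the description forms, Hccs was 1.59-fold higher on the 77 arrays of form 2 than on the 215 of form 1 (0.203 ± 0.00776 log10 units, SE; limma adjusted p = 4.17e-74), and all 77 were above the form 1 median. Eif2s3y was 19.6-fold higher (1.29 ± 0.0925, adjusted p = 1.65e-30) and Kdm5d 7.52-fold higher (0.876 ± 0.0669, adjusted p = 2.05e-27), each with 76 of 77 above that median. Gata3 (1.19-fold, adjusted p = 4.92e-19, 75 of 77) and the cyclin gene Ccne1 (1.1-fold, adjusted p = 1.89e-18, 74 of 77) were also higher. The X-linked RNA helicase gene Ddx3x was 1.33-fold lower on form 2 (-0.124 ± 0.0103, adjusted p = 1.19e-23, 74 of 77 below the form 1 median), as were Gpbp1 (1.27-fold, adjusted p = 4.84e-17, 75 of 77), Ttc3 (1.33-fold, adjusted p = 6.54e-17, 76 of 77), Pcp4 (1.29-fold, adjusted p = 1.91e-16, 75 of 77) and Naca (1.26-fold, adjusted p = 2.38e-16, 76 of 77). Over all probes 10695 differed, 5844 higher and 4851 lower on form 2.

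Form 2 is identical with batch B, and the arrays of form 1 are those of batches A and C, so the form could be compared with batch A alone. For Eif2s3y 98.6% of batch A had the low level and 98.7% of batch B the high one. The comparison with batch A therefore cannot tell a batch from the Y-linked level, or from sex so far as sex follows that level. Against batch A 252 probes differed, 119 higher and 133 lower on form 2. No other splits of these arrays were run, so this count has no chance value. Gpbp1 (adjusted p = 0.936), Ttc3 (0.998), Pcp4 (0.951), Naca (0.952) and Gata3 (0.519) no longer passed. Eif2s3y was 70.8-fold higher (1.85 ± 0.0393, adjusted p = 2.39e-88), Kdm5d 21.6-fold and Hccs 1.49-fold, each in all 77 arrays of form 2 against the batch A median, and Ddx3x was 1.32-fold lower in 73 of 77. Named after their values were seen, the kinase gene Blk was 2.25-fold higher, the spermatid genes Gm20747 and Ssty1 1.92-fold and 1.7-fold higher, and the X-linked genes Kdm6a and Eif2s3x 1.33-fold and 1.13-fold lower. Between batches A and C, both of form 1, 14677 probes differed.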

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

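All tests in this part were chosen only after the results they concern had been seen, and the explanations are hypotheses found and tested on the same mice. Other assignments of the arrays gave far smaller counts than the real ones. Of 100 orders of the mouse numbers, the real one included, 1 gave as many probes with a trend as the 14680 observed, namely the real one, and the highest of the others gave 4835. Of 100 splits of the arrays into 77 and 215, 1 gave as many probes as the 10695 between the description forms, again the real one, and the highest of the others gave 901. Chance can thus be excluded for both counts as such. Orders that call 4835 probes point to a structure of the arrays, and the step between batches A and C, at 14677 probes, is of the size of the trend itself.

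Batch C lay away from the pool while batches A and B, when pooled, averaged close to it. Over the 151 mice of A and B, 64 probes had a mean linear ratio more than 1.2-fold from 1, against 1903 over the 141 mice of C, and with the sign turned the counts were 232 and 1870. The level of the Y-linked genes, and with it sex so far as sex follows that level, was argued against as the whole source: 98.6% of batch A had the low level and 98.7% of batch B the high one, and by the mean log ratio, whose size does not depend on direction, they had 49 and 57 probes beyond 1.2-fold against 1639 in batch C. A candidate explanation is a pool that held RNA of the mice of A and B only (64 probes), although the labels describe portions of every sample. It cannot be told apart from a change of reagents or processing limited to the arrays of batch C, since the direction of the ratio is not settled and both would leave A and B nearer the pool; open too is the cross direction of the mice, which is not labelled per mouse and was untested.

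Pituitary genes fell into a low and a high cluster, with Prl, Gh, Cga, Tshb and Pitx1 high in the same mice. An array batch, or the level of the Y-linked genes, and with it sex so far as sex follows that level, was argued against as the whole source, since 36.5% of batch A and 26% of batch B, which have opposite Y-linked levels, were in the high cluster. Regulation of a single hormone was argued against, since each pair of clustered genes of different hormones matched in at least 88.4% of mice (Prl and Tshb). Pituitary tissue left on part of the brains, a sampling difference, may give such a match (lowest over all pairs 88.4%). Lhb, another hormone gene, had a single level with an SD of 0.0362, under the median probe SD of 0.0495. In batch B Prl was above 0 in 3 of 77 mice against 20 each for Gh and Cga. In batch A it was above 0 in 28 of 74, against 21 each. As these batches have opposite Y-linked levels, Prl may differ with that level, and its counts do not weigh against tissue. The signal of the Lhb probe is unknown. Pituitary tissue and a shared regulator of the 5 genes thus cannot be told apart here, and cross direction, not labelled per mouse, was untested.

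Probes with 3 clusters were called in each batch alone in 43 of 94 cases, which argues against array batch as the source for these 43, of which 4 depart from 1:2:1. For the other 51, of which 25 depart, a batch stays open, since 33 of them were called with each probe centred within the batches and the rest were not. Genotype at a locus near the gene may account for part of them: the median squared r of such genes was 0.66 over the 9 pairs up to 50 genes apart, as for Scg5 and Aqr, against 0.0026 over 845 pairs on different chromosomes, whose 95th percentile was 0.037. Some of the 9 pairs share a gene, so they are not independent, and their values ran from 0.0003 (Cga and Sit1) to 0.819. The highest pair on different chromosomes had 0.692. Whether genotype near the gene, not used here, changes expression or only the binding of a probe cannot be told apart here. Of 13 other probes of 7 such genes, 30.8% had r over 0.5, near the 34.1% of all pairs of probes of 1 gene, from 0.998 for Bpnt1 to -0.536 for a probe of Ybx1, and another probe of Ybx1 had 0.905.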

How the results depend on the processing

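Settings that name a single batch, batch centring, batch as a covariate or form 2 against batch A alone were chosen after seeing the data, and the others before. Among single genes, lists and pairs, 2477 values stayed on their side of the threshold, 132 lost their call, 37 gained one, 62 moved and 42 changed sign. A change of sign counts only where a value passed its test in at least 1 of the settings compared; of 343 values that passed in neither, 70 had the other sign. Among the counts and shares that answer a comparison, 68 stayed within 1.5 times, 26 moved, 3 lost their call, all against circular shifts, and 1 crossed over. The cause was not tested for any of these, except that single batches and forms hold fewer arrays and the SD filter tests fewer probes. No paired analysis was possible because all mice form 1 group. The signal over background is unknown, so its limits could not be stated.

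The 138 probes away from the pool became 346 with array weights, 460 in form 1, 33 in form 2, 16104 with no fold threshold, 33 in batch A and 1638 in batch C. The 14680 trends over mouse number became 7959 after the SD filter, 4248 with batch as a covariate, and 3003, 5087 and 5968 in batches A, B and C. The 10695 probes between the forms became 6155 after the SD filter, 1837 with mouse number as a covariate and 252 against batch A alone. The 1547 clustered probes became 3665 with a separation of 2 SDs, 114 with 4 SDs, 308 with unequal variances, 967 with arrays scaled to equal spread, 620 in form 2 and 483 in batch A. Of the 308, 168 are among the 1547, of the 967, 589, and batch centring kept 887 of the 1547. The 94 probes with 3 clusters became 302, 14, 82, 56, 93 and 109 in these settings in turn, 135 with batch centring and 176 in batch C. The 165 relations between lists became 79 in form 2, 74 in batch A and 90 in batch C.

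Against circular shifts of the gene order, which are void as a chance value, the mean squared r of neighbours was 0.0719 in form 1 (p = 0.0891), 0.0517 without the first principal component (p = 0.099) and 0.0656 in batch C (p = 0.228). Against random gene orders, whose highest values were 0.0613, 0.0436 and 0.0575, each of these 3 passed (p = 0.0099, the smallest they can give). The 65.7% of probes nearer 1 as deposited became 55.9% over the top 5%, 46.1% over all probes and 75% over batches A and B. A different measure, the share of 3-cluster probes whose lowest and highest linear ratios sum to within 0.2 of 2, was 90.4% as deposited and 27.7% with the sign turned. That measure and the use of batches A and B alone were chosen after seeing the data.

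Means against the pool changed sign in form 2 for Zfp638 (-0.00601), Postn (-0.00704), Rb1cc1 (-0.00349), Eif2s3y (0.253) and Kdm5d (0.233), and in batch A for Zfp638 (-0.0153), Postn (-0.0139), Rb1cc1 (-0.014) and Gm14288 (-0.00244). Trends over mouse number changed sign in batch B for Ttc3 (-0.00394), Anapc16 (-0.00651) and Ofd1 (-0.00172), and in batch A for Anapc16 (-0.00819).

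The r of a gene with the rest of its list changed sign without the first principal component for Mal (0.322), Gja1 (0.222), Ctss (0.446), Foxj1 (0.143), Tac1 (0.0918), Tdo2 (0.0247) and Rpl13 (0.171). It did so in batch C for Ctss (0.254), Foxj1 (0.24), Lss (0.235), Rpl13 (0.116), Ddx3x (0.225) and Kdm6a (0.0826), and in batch A for Mia (-0.052), Tac1 (0.14), Ddx3x (0.352), Kdm6a (0.0407) and Eif2s3y (0.268). Form 2 turned Foxj1 (0.012) and Eif2s3y (0.257), and form 1 turned Ddx3x (0.31) and Kdm6a (0.0386). Regression on the sex chromosome probes turned Ddx3x (0.391), Kdm6a (0.106) and Eif2s3x (0.108). Batch centring turned Mal (0.137) and Ddx3x (0.128), removal of the mouse number trend turned Mal (0.14), and ranks turned Calb1 (-0.0116, with each gene ranked before the list is averaged, against -0.0723 with the finished list score ranked).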

Other observations

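The values in this part were picked after the data were seen, and no test was run on them beyond those named. Between form 2 and batch A, further genes differed by limma beyond those already named. These arrays also have opposite levels of the Y-linked genes, so batch and that level cannot be told apart. The epigenetic regulator gene Uhrf1 was 1.27-fold higher on form 2 (0.104 ± 0.0106 log10 units, SE; n = 77 and 74; adjusted p = 9.79e-15; 74 of 77 above the batch A median), the retinal matrix gene Impg1 1.39-fold higher (adjusted p = 1.47e-11, 70 of 77), the glycine receptor subunit gene Glrb 1.31-fold higher (adjusted p = 3.2e-11, 67 of 77) and Sytl4 1.22-fold higher (adjusted p = 4.19e-14, 71 of 77). Clec18a was 1.23-fold lower (adjusted p = 1.38e-14, 74 of 77 below that median), Spag6l 1.14-fold lower (adjusted p = 2.09e-08, 69 of 77), and the retinoid genes Rlbp1 and Rdh5 1.15-fold and 1.12-fold lower (adjusted p = 2.93e-07 and 2.46e-06, 64 and 65 of 77). In batch C the mean of Glrb was 0.0576, beside -0.0646 in batch A and 0.0541 in batch B, and that of Uhrf1 was 0.007, beside -0.0629 and 0.0409.

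Mouse 78 and mouse 108 had low values for all 14 measured cerebellar genes. Crtam was at -1.23 and -1.07 (median of all mice 0.0532), En2 at -0.977 and -0.841 (median -0.0448), Il16 at -0.758 and -0.628 (median -0.0048), Gdf10 at -0.72 and -0.583 (median -0.017) and Cbln1 at -0.61 and -0.648 (median -0.0322). Zic1 was at -0.571 and -0.438, Slc1a6 at -0.409 and -0.387, and Pvalb, which neurons outside the cerebellum also express, at -0.156 and -0.197.

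A single mouse of batch A had the high level of the Y-linked genes, with 0.326 for Eif2s3y and 0.298 for Kdm5d, and a single mouse of batch B had the low level, with -1.6 and -1.04. The mean linear ratio of Prl was 1.13 in batch A, 0.198 in batch B and 1.2 in batch C, and that of Gh was 0.891, 1 and 1.7. Among genes with 3 clusters on the same chromosome, the largest squared r values were 0.819 for Scg5 and Pla2g4e on chromosome 2 (40 genes apart), 0.787 for Rps3 and Myo7a on chromosome 7 (11 apart) and 0.733 for Ccr6 and Wtap on chromosome 17 (14 apart).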
